A study of Homo sapiens with 16 samples.

How the data were processed

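The intensities in the raw files were made before deposit by Agilent Feature Extraction 12.1.1.1 with the protocol GE1_1200_Jun14, per the file headers, which gives a background-subtracted processed signal for each spot. The log2 values of the series matrix were made by the submitters before deposit, and the deposited processing notes name limma only. Their ranks matched those of the median signal less the median background exactly, and the arrays had near-identical quantiles, with medians from 5.827 to 5.868. Per the labels' protocols, cells grew in phenol-red-free medium with charcoal-stripped serum and 10 nM estradiol, and 100 ng of RNA with a RIN above 8 was labelled with Cy3. Per the file headers the array design was annotated on hg19. In 3 files the signals had been saved again with rounding.

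Analyses used R 4.3.3 with limma 3.58.1 and the package data.table (1.17.8), and Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9. The samples, 5 comparisons and the other settings, except those named below as added, were fixed before the data were examined. The comparison of alternating with long-term palbociclib cells was added after the slides were seen and was adjusted on its own.

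The processed signal was put on the log2 scale and the 75th percentile of each array was subtracted. Of 58201 probes that were not controls, 29748 were well above background on all arrays of at least 1 group and were kept. Spots marked as outliers by the feature extraction were left out, which removed 4.285% of gene values. The probes had to be named from accessions and 34892 of 58201 could be. Of the kept probes 21877 had a gene symbol, and 7871 did not and were not analysed here beyond the counts given in the closing part. The probe with the highest mean stood for its gene, which left 16500 genes. Among 188 checks of named genes on their other probes, 18 gave the opposite sign. In 11 of these the gene had been called, and in 5 of them the other probe also lay beyond 0.5 on the log2 scale.

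Differences were tested in limma over all 16 arrays with 4 group means and moderated t statistics, adjusted by Benjamini-Hochberg in each comparison. A gene was said to rise or fall at an adjusted p under 0.05. No minimum fold change was required, and genes of at least 2-fold are counted apart. Folds are given with the standard error from limma. Where a gene was above background on 0 arrays of a group, only an at-least fold is given. For this, each value of the dim group below the lowest signal that counted as well above background on its array was raised to that signal. These bounds hold on the scale of the processed signal only, since normexp with its offset compresses dim signals and gave a smaller change than the bound for each such gene named in the text.

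Lists were tested with camera in limma at an inter-gene correlation of 0.01, adjusted over 23 lists and all planned comparisons, and again with the correlation estimated from the data. Calls in a list are also given adjusted over the list alone. The lists were written from general knowledge: Mitosis and G2/M, DNA replication and S phase, cyclins with CDKs, inhibitors and RB/E2F, replication-dependent histones, ribosome biogenesis and MYC targets, estradiol-induced genes, genes lower under estradiol, luminal, basal and mesenchymal identity, receptor tyrosine kinases, interferon-stimulated genes, antigen presentation, senescence-associated secreted factors, p53 targets, hypoxia, the unfolded protein response, cholesterol biosynthesis, lysosome and autophagy, drug efflux and metabolism, and markers of fibroblasts, endothelium and leukocytes.

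Named genes followed a rule. It took the 5 largest rises and falls that passed, did not overlap and lay above background on all arrays of both groups. It added the 2 largest in each direction that were not above background in 1 group, up to 3 members of each list with the smallest adjusted p, and a fixed panel of 18 genes. The text names part of these, with lists that passed first, and leaves the rest to the tables. Of the genes the rule chose, 1 was withheld from the text throughout.

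Dark areas were found on tiles of 16 rows by 8 columns of spots, 480 per array, from 18549 bright spots. A tile was dark where the median of its spots lay below the median over arrays by more than 0.5. Dark spots were left out in an alternative written after the arrays had been seen.

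The method was tested on simulated data for 10-week palbociclib against parental cells, with known changes in 50 genes of each size. The simulated arrays took the parental means and the spread of the 4-group fit, with noise independent between genes. The method recovered 0% at 1.5-fold, 2% at 2-fold, 62% at 4-fold and 82% at 8-fold. Of 15860 unchanged genes 2 were called. A moved list had a camera adjusted p of 3.26e-45, and 0 of 22 other lists passed. The simulation held no correlated genes and no dark areas, so these values do not cover them.

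Alternatives tried were quantile normalization, normexp with an offset of 50 on the median signal (the files have no mean signal), the series matrix values and median centring. Others were no filter on dim probes, probes well above background on all 16 arrays, the mean of a gene's probes, a replicate block, slide as a block, a trend with robust variances, array weights, outlier spots kept, and only the groups compared. Lists were also tested with fry. Each array was left out in turn. Alternatives added after the data were seen left out the dark areas, with and without quantile normalization, left out the darkest arrays, or scaled over probes detected on all arrays. Control spots and probes without a gene name were left out of the gene counts.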

Results

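Total RNA from MCF7 cells, an established oestrogen receptor positive breast cancer line, was measured on 16 single-colour arrays in 4 groups of 4 biological replicates per the labels. Parental cells received the vehicle, 0.04% DMSO. The 10-week palbociclib cells were grown in palbociclib at 750 nM for 10 weeks. The alternating cells received palbociclib at 750 nM for 1 week and fulvestrant, given in the labels under its ICI code, at 750 nM for the next, over 10 weeks. The long-term palbociclib cells were kept in palbociclib at 500 nM for more than 24 weeks. Palbociclib inhibits the kinases CDK4 and CDK6, which release cells from G1, and fulvestrant is an oestrogen receptor antagonist that leads to loss of the receptor. Every group was cultured with estradiol. The series title sets palbociclib alone against the alternating schedule, and the labels do not say which drug the alternating cells were in at harvest.

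Each array held 62976 spots, of which 60901 were not controls. The 75th percentile of the processed signal ranged from 236 to 954.9 intensity units with a median of 459.2, and 40.96% to 65.47% of probes were well above background. The alternating arrays had the highest shares well above background, 57.69% to 65.47%. The number of arrays limits the precision of every value below. No spot was saturated and no array pair held identical values.

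The arrays lay on 2 slides. Slide 1 held the parental and the 10-week palbociclib arrays, and slide 2 held the alternating and the long-term palbociclib arrays. Slide and treatment therefore cannot be told apart in the comparisons that cross slides. The contrast of alternating with long-term palbociclib cells was added for this reason after the slides were known, because both groups lay on slide 2.

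Areas of some slide 1 arrays were dark. An area was counted as dark where its bright spots lay below their median over all arrays by more than 0.5 on the log2 scale. Dark areas covered 27.24% of 10-week palbociclib array 3, 16.26% of parental array 2, 5.894% of parental array 1, 1.626% of parental array 4 and 0.813% of 10-week palbociclib array 1. The other arrays had none. The mean correlation of 10-week palbociclib array 3 with its own group was 0.862, and it was 0.981 when the dark spots were left out.

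**Figure D1:**
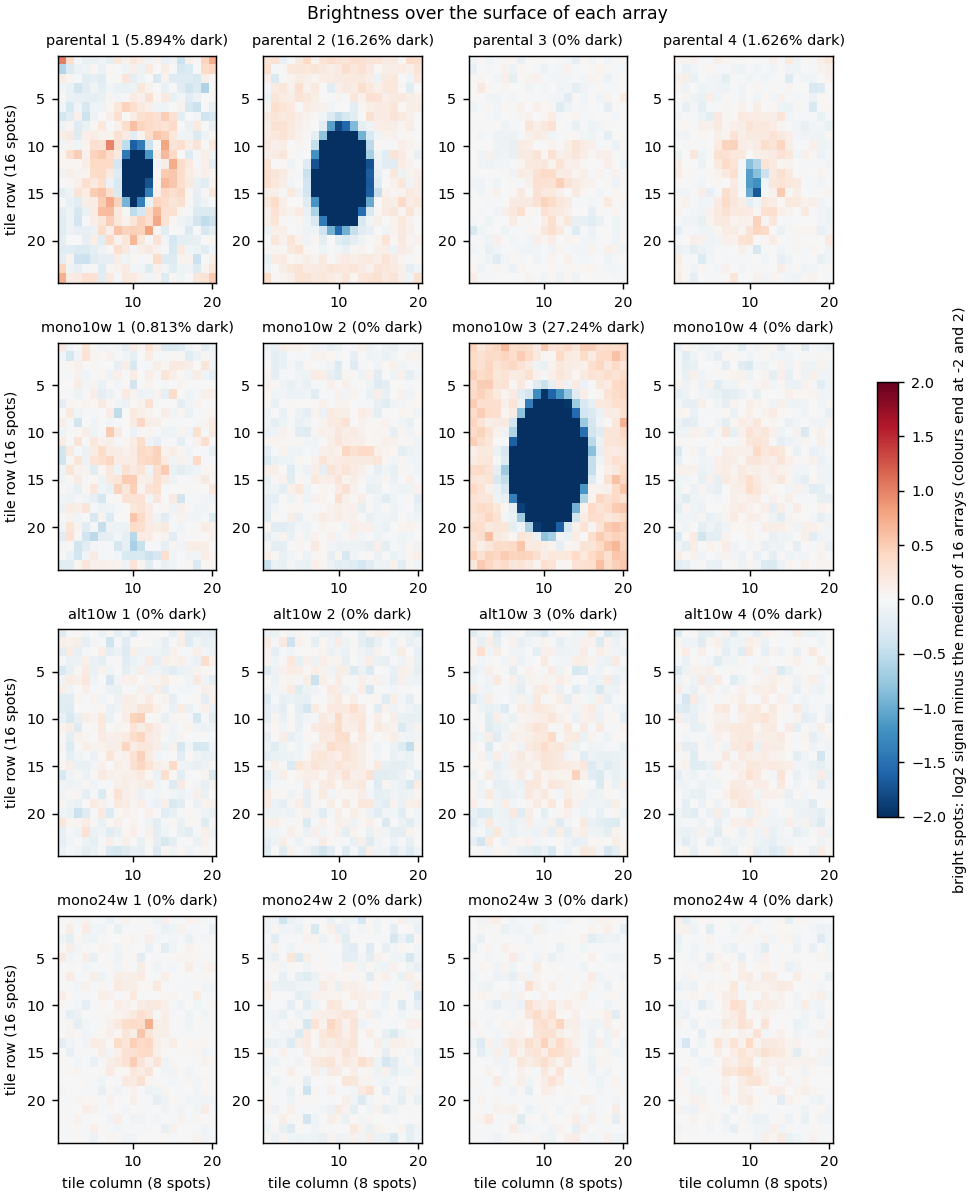
Brightness of the tiles of each of the 16 arrays as the log2 difference of bright spots from their median over all arrays, by spot row and column. Dark areas cover 27.24% of 10-week palbociclib array 3 and 16.26% of parental array 2, and no array of slide 2 has any.

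Genes called by limma at an adjusted p under 0.05 numbered 1676 in the 10-week palbociclib cells, 3974 in the alternating cells and 1904 in the long-term palbociclib cells, each against parental cells. They numbered 2601 between alternating and 10-week palbociclib cells, 3497 between long-term and 10-week palbociclib cells, and 2643 between alternating and long-term palbociclib cells. With the dark areas left out the counts were 4280, 6705, 4396, 5289, 6364 and 6044 in the same order. Of the genes first called, 96.84%, 97.48%, 97.27%, 97.5%, 96.74% and 99.96% were called again in the same direction, and 0 in the opposite one. Of the called genes chosen by the naming rule, those with a value on all 8 arrays (52, 67, 64, 63, 66 and 69) lay in the called direction on 4 of 4 treated arrays, as did the scores of the called lists. Selection largely fixed this.

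**Figure D2:**
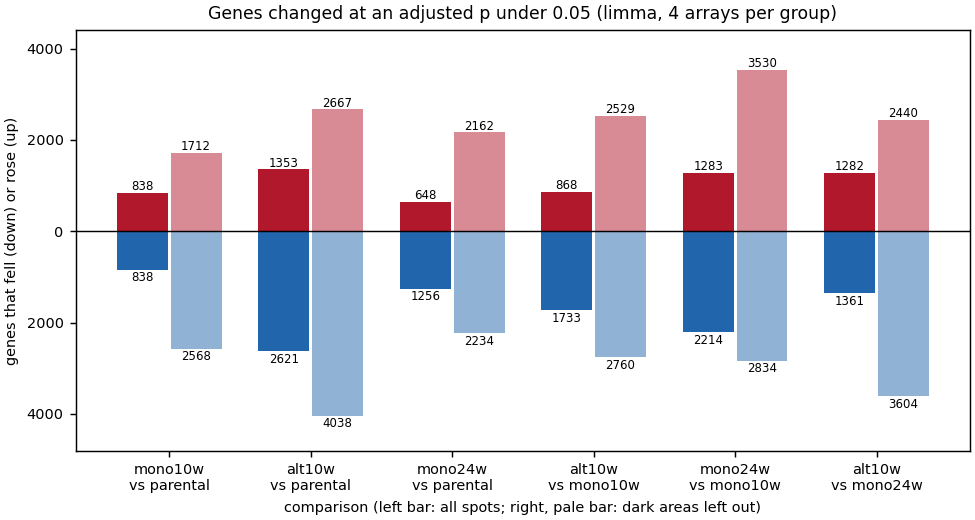
Number of genes that rose (above 0) and fell (below 0) in each of the 6 comparisons, with all spots and with the dark areas left out. Leaving out the dark areas takes the count from 1676 to 4280 in 10-week palbociclib against parental cells.

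**Figure D3:**
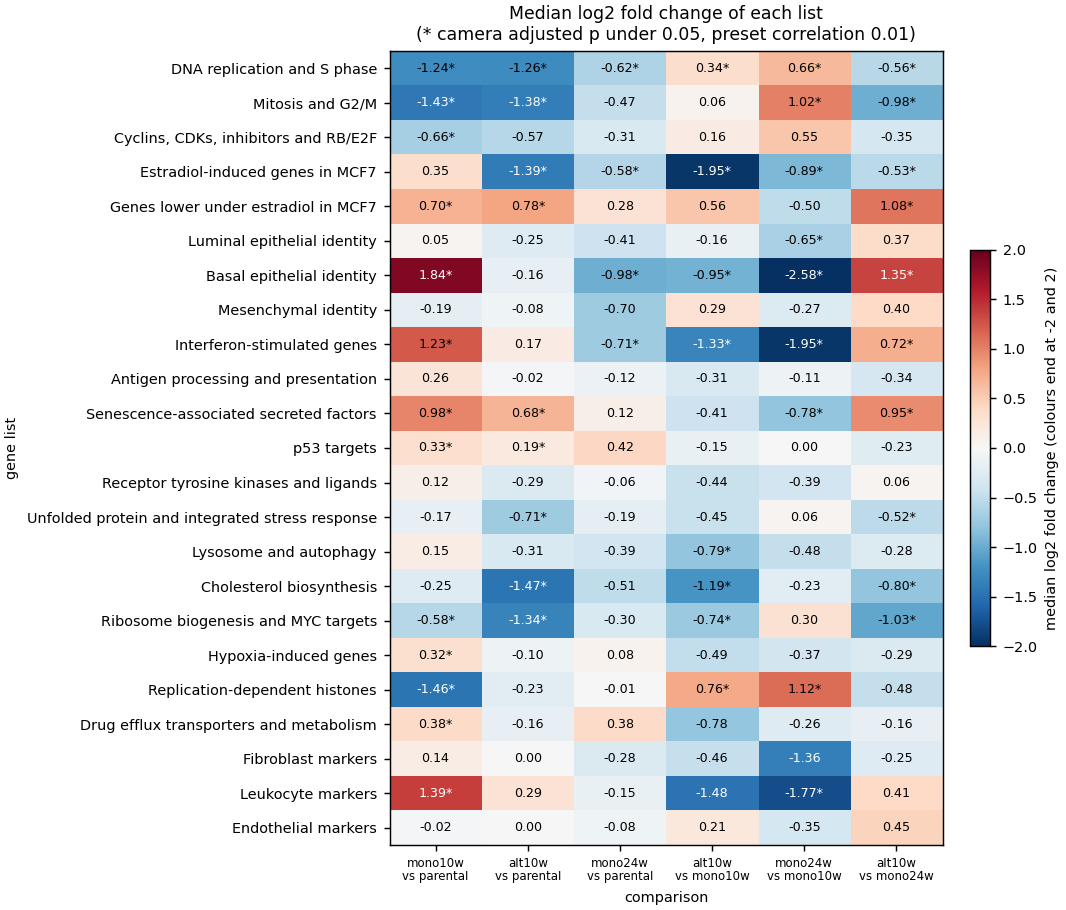
Median log2 fold change of 23 gene lists (vertical) in the 6 comparisons (horizontal), where a star marks a camera adjusted p under 0.05. The mitosis list reads -1.43 in 10-week palbociclib against parental cells and 1.02 in long-term against 10-week palbociclib cells.

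The first comparison asked what 10 weeks of palbociclib changed relative to vehicle. Genes of mitosis and DNA replication were lower in the 10-week palbociclib cells, and interferon-stimulated and basal epithelial genes were higher. These list calls were lost with an estimated correlation (camera adjusted p = 0.159 to 0.228). FOXM1, the transcription factor of the G2/M programme, fell by 2.41 ± 0.26 on the log2 scale (SE, 3 and 4 arrays), and CMPK2, an interferon-induced mitochondrial kinase, rose by 2.59 ± 0.25 (4 and 4 arrays). Their limma adjusted p-values were 5.86e-05 and 1.36e-05. Of 16065 genes tested 838 rose and 838 fell, and 1618 of them changed at least 2-fold.

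Among the 50 mitosis and G2/M genes 33 fell and 0 rose, 45 and 0 adjusted over the list alone, with a median log2 fold change of -1.43 (camera adjusted p = 4.7e-18, adjusted p = 0.186 with an estimated correlation). CDK1, the kinase that drives entry into mitosis, fell by 2.08 ± 0.28 and NDC80, a kinetochore protein, fell by 1.83 ± 0.24 (limma adjusted p = 0.000261 and 0.00018). Of the 47 DNA replication genes 24 fell and 0 rose, 35 and 0 adjusted over the list alone, with a median of -1.24 (camera adjusted p = 6.84e-15, adjusted p = 0.228 with an estimated correlation). EXO1, a DNA repair exonuclease, fell by 1.79 ± 0.23, and DHFR, which supplies folate for thymidylate synthesis, fell by 2.74 ± 0.41 over 3 parental values (limma adjusted p = 0.000137 and 0.000745). In the list of cyclins, CDKs, inhibitors and RB/E2F 10 of 35 genes fell and 0 rose, 12 and 0 adjusted over the list alone, with a median of -0.66 that normexp brought to -0.35 (camera adjusted p = 0.00242, adjusted p = 0.366 with an estimated correlation). E2F2, a transcription factor of S phase genes, fell by 2.11 ± 0.39 and CDK2, a kinase of S phase entry, by a log2 fold change of -1.55 ± 0.38 (limma adjusted p = 0.00288 and 0.0163). E2F1 had -1.37 ± 0.35 (limma adjusted p = 0.0211) with 10-week palbociclib array 3 apart at 2.47, or 1.39 on that array without the dark areas. CCNE1 had -1.03 (limma adjusted p = 0.0844), or -0.59 without the dark areas, with parental array 1 apart at 5.29. MKI67, a proliferation marker, had -1.38 ± 0.37 (limma adjusted p = 0.0285), and its call was lost without parental array 1 (-1.12), 10-week palbociclib array 2 (-1.24) or array 4 (-1.09). The call of E2F1 was likewise lost without parental array 1 (-1.30) or 2 (-1.25) and without 10-week palbociclib array 1 (-1.23), 2 (-1.24) or 4 (-1.30).

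Replication-dependent histones fell as a list, with 7 of 21 genes lower and 1 higher, 12 and 1 adjusted over the list alone, and a median of -1.46 that was -0.79 without the dark areas and -0.72 with array weights (camera adjusted p = 0.00364, adjusted p = 0.63 with an estimated correlation). The core histones H4C2 and H3C4 had log2 fold changes of -2.51 ± 0.51 and -2.04 ± 0.45 (limma adjusted p = 0.00531 and 0.0084). The ribosome biogenesis and MYC list had a median of -0.58 with 2 of 32 genes lower and 0 adjusted over the list alone (camera adjusted p = 0.00522, adjusted p = 0.676 with an estimated correlation). MYC itself had -0.20 and did not pass.

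Interferon-stimulated genes rose, 20 of 42 with 0 falling and 23 adjusted over the list alone, with a median of 1.23, or 1.20 with genes below background at their bound (camera adjusted p = 8.29e-15, adjusted p = 0.21 with an estimated correlation). IFIT3, an antiviral effector, rose by 3.90 ± 0.41, or 2.10 under normexp, with 2 of 4 parental arrays above background (limma adjusted p = 2.86e-05). SAMD9, another antiviral factor, was not well above background on any parental array and was at least 9.23-fold higher (limma adjusted p = 1.37e-07).

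Basal epithelial genes rose, 8 of 16 with 0 falling and 8 adjusted over the list alone, with a median of 1.84 (camera adjusted p = 8.25e-06, adjusted p = 0.159 with an estimated correlation). That median was 1.15 under normexp, 0.44 with no filter on dim probes and 1.20 over probes well above background on all 16 arrays. The phospholipid-binding protein ANXA1 rose by 2.64 ± 0.37 and the integrin ITGB4, part of hemidesmosomes, by 2.06 ± 0.33 (limma adjusted p = 0.000342 and 0.000879). Genes reported to be lower under estradiol rose, 7 of 20 with 1 falling, 9 and 2 adjusted over the list alone, with a median of 0.70, or 0.50 at the bounds (camera adjusted p = 0.00109, adjusted p = 0.319 with an estimated correlation). TXNIP, a thioredoxin inhibitor, rose by 2.47 ± 0.30, PSCA, a cell surface antigen, by 2.33 ± 0.36 and TP53INP1, a p53-induced stress protein, by 2.49 ± 0.41 (limma adjusted p = 9.02e-05, 0.000713 and 0.00124). Estradiol-induced genes did not pass, with 3 higher and 3 lower of 44 and a median of 0.35 (camera adjusted p = 0.0921), but passed without the dark areas (0.0341) and after quantile normalization (0.0295). PGR, the progesterone receptor and an oestrogen receptor target, had 0.24 (adjusted p = 0.807), ESR1, the receptor gene, 0.62 (0.251) and CCND1, cyclin D1, 0.57 (0.246). Without 10-week palbociclib array 3 these were 0.10, 0.35 and 0.33.

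Senescence-associated secreted factors rose, 5 of 18 with 0 falling, 5 and 1 adjusted over the list alone, with a median of 0.98 (camera adjusted p = 0.000321, adjusted p = 0.159 with an estimated correlation). Under normexp this median was 0.62, and with no filter on dim probes it was 0.30. PLAT, tissue plasminogen activator, was at least 6.64-fold higher (limma adjusted p = 4.67e-06). Drug efflux and metabolism genes rose, 4 of 21 with 0 falling and 5 adjusted over the list alone, with a median of 0.38, or 0.44 at the bounds (camera adjusted p = 0.0164, adjusted p = 0.21 with an estimated correlation). That list's median was 0.62 without parental array 1 and 0.60 without 10-week palbociclib array 4, and lower without 10-week palbociclib array 1 (0.25), array 2 (0.23, adjusted p = 0.0567) or array 3 (0.22). UGT2B15, which conjugates steroids, rose by 4.90 ± 0.39 over 3 treated values (limma adjusted p = 3.63e-06). The p53 target list had a median of 0.33 with 3 of 30 genes higher and 3 adjusted over the list alone (camera adjusted p = 0.0185, adjusted p = 0.766 with an estimated correlation), 0.11 without 10-week palbociclib array 3 (0.0777) and 0.54 without parental array 2. The hypoxia list had a median of 0.32 with 2 of 24 higher, 5 and 1 adjusted over the list alone (camera adjusted p = 0.0353, adjusted p = 0.652 with an estimated correlation). It lost its call without parental array 1 (0.34), 3 (0.30) or 4 (0.16) and turned to -0.01 without 10-week palbociclib array 3, while its median was 0.48 without parental array 2 and 0.48 without 10-week palbociclib array 1.

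Leukocyte markers had a median of 1.39 over 5 genes, with 1 higher and 1 adjusted over the list alone (camera adjusted p = 0.0142, adjusted p = 0.228 with an estimated correlation). With the dark areas left out this median was -0.33 (0.956), without parental array 2 it was 0.48 (0.757), and without parental array 3 it was 2.17. Fibroblast markers (median 0.14 over 4 genes) and endothelial markers (-0.02 over 5) did not pass, with 0 genes called. Luminal epithelial genes had a median of 0.05 over 25 genes (-0.00 without the dark areas), lysosome and autophagy 0.15 over 34, antigen presentation 0.26 over 20, cholesterol biosynthesis -0.25 over 23, the unfolded protein response -0.17 over 29, mesenchymal genes -0.19 over 16 and receptor tyrosine kinases 0.12 over 28, all with camera adjusted p at or above 0.144. The luminal list passed without the dark areas (0.0341) and after quantile normalization (0.0389), and the lysosome list in the series matrix values (0.045). TSPAN1, a luminal tetraspanin, rose by 2.89 ± 0.45, and ERBB4, a neuregulin receptor, rose by 2.21 ± 0.35 (limma adjusted p = 0.000745 and 0.000951). TGFB2, a transforming growth factor, fell by 2.50 ± 0.37 (limma adjusted p = 0.000515). Among the largest falls was that of ACTG2, a smooth muscle actin, which fell by 7.46 ± 0.46 (limma adjusted p = 1.37e-07). FST, an activin antagonist, fell by 4.58 ± 0.51, and the keratin KRT9 rose by 6.06 ± 0.44 (limma adjusted p = 5.06e-05 and 1.04e-06). BCAT1, which transaminates branched-chain amino acids, was at least 9.16-fold lower (limma adjusted p = 2.86e-05).

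The 1676 calls became 3806 without 10-week palbociclib array 3 and 249 in a fit of these groups alone, in which E2F1, MKI67, ITGB4, DHFR, E2F2, CDK2, H4C2 and H3C4 kept their values and lost their calls. Both groups lay on slide 1, and the main fit shared its spread with slide 2. The fit with slide as a block gave 1676 by construction and tests nothing.

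The next comparison asked what the alternating schedule changed relative to vehicle. Estradiol-induced genes, mitosis, DNA replication, ribosome biogenesis and cholesterol biosynthesis were lower in the alternating cells, and genes reported to be lower under estradiol were higher. With an estimated correlation none of these lists passed (camera adjusted p = 0.21 to 0.497). PGR fell by 5.91 ± 0.52 on the log2 scale (SE, 3 and 4 arrays, 3 of 4 alternating arrays above background), and AREG, an EGFR ligand induced by estradiol, fell by 8.60 ± 0.67 (4 and 4 arrays). Their limma adjusted p-values were 6.04e-06 and 1.34e-06. Of 16394 genes 1353 rose and 2621 fell, 3647 of them at least 2-fold. The excess of falls turned to a share of 64.2% rising when the scaling used only probes detected on all arrays.

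Of 45 estradiol-induced genes 28 fell and 1 rose, 31 and 2 adjusted over the list alone, with a median of -1.39 (camera adjusted p = 1.34e-08, adjusted p = 0.25 with an estimated correlation). PKIB, a protein kinase A inhibitor, fell by 3.30 ± 0.30 and GREB1, a coregulator induced by the receptor, fell by 4.38 ± 0.96 (limma adjusted p = 5.58e-06 and 0.0047). GREB1 read 4.74 on alternating array 2 against 2.42 to 2.77 on the other alternating arrays. TFF1, a classic estradiol target, had -0.19 (adjusted p = 0.765) and did not pass. ESR1 had 1.13 ± 0.32 (limma adjusted p = 0.0202), a call lost without parental array 3 (1.03) or alternating array 1 (1.12), 3 (1.05) or 4 (1.06), and 1.71 with the dark areas left out and quantile normalization. Genes reported to be lower under estradiol rose, 10 of 21 with 1 falling, 11 and 1 adjusted over the list alone, with a median of 0.78 (camera adjusted p = 3.96e-06, adjusted p = 0.21 with an estimated correlation). PSCA rose by 4.84 ± 0.36, BLNK, a B cell linker protein, by 2.59 ± 0.44 and YPEL3, a growth suppressor, by 1.73 ± 0.29 (limma adjusted p = 1.04e-06, 0.000987 and 0.000937).

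Of 50 mitosis genes 38 fell and 0 rose, 38 and 0 adjusted over the list alone, with a median of -1.38 (camera adjusted p = 4.24e-10, adjusted p = 0.269 with an estimated correlation). AURKA, a spindle kinase, fell by 2.43 ± 0.39, CCNA2, cyclin A2, fell by 2.28 ± 0.33 and MKI67 fell by 1.94 ± 0.40 over 3 alternating values (limma adjusted p = 0.00066, 0.00036 and 0.00384). Of 47 DNA replication genes 26 fell and 0 rose, 30 and 0 adjusted over the list alone, with a median of -1.26 (camera adjusted p = 2.85e-06, adjusted p = 0.497 with an estimated correlation). ORC6, of the origin recognition complex, fell by 1.89 ± 0.34 (limma adjusted p = 0.00138). The cyclin and CDK list did not pass, with 9 of 35 lower and a median of -0.57 (camera adjusted p = 0.0532), though CDKN3, a CDK phosphatase, fell by 2.36 ± 0.40 and SKP2, a ubiquitin ligase subunit, fell by 1.74 ± 0.40 (limma adjusted p = 0.000987 and 0.00592). That list passed with the dark areas left out (0.00999, with 16 genes lower), without parental array 2 (0.0242) and without alternating array 4 (0.0484).

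In the ribosome biogenesis and MYC list 22 of 32 genes fell and 0 rose, 22 and 0 adjusted over the list alone, with a median of -1.34 (camera adjusted p = 1.05e-06, adjusted p = 0.388 with an estimated correlation). RRS1, a ribosome assembly factor, fell by 2.18 ± 0.37 and MYC, the transcription factor of growth genes, fell by 1.90 ± 0.35, with alternating array 2 apart at 3.46 against 2.82 to 2.86 (limma adjusted p = 0.00113 and 0.00172). Cholesterol biosynthesis fell, 14 of 23 with 0 rising and 15 adjusted over the list alone, with a median of -1.47 (camera adjusted p = 0.000342, adjusted p = 0.388 with an estimated correlation). HMGCR, the rate-limiting enzyme of that pathway, fell by 1.78 ± 0.34, or -1.15 with the dark areas left out and quantile normalization (limma adjusted p = 0.00226). The unfolded protein list had 12 of 30 genes lower and 1 higher, 12 and 1 adjusted over the list alone, with a median of -0.71 (camera adjusted p = 0.0257, adjusted p = 0.633 with an estimated correlation). It did not pass after quantile normalization (-0.32, adjusted p = 0.23), normexp (-0.24) or in the series matrix values (-0.25). PSAT1, of serine synthesis, fell by 2.41 ± 0.33 over 3 parental values (limma adjusted p = 0.000309).

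Senescence-associated secreted factors rose, 5 of 18 with 0 falling and 5 adjusted over the list alone, with a median of 0.68, or 0.35 at the bounds (camera adjusted p = 0.00735, adjusted p = 0.228 with an estimated correlation). With no filter on dim probes the median turned to -0.24 (adjusted p = 0.0986). ICAM1, an adhesion molecule, rose by 1.51 ± 0.35 (limma adjusted p = 0.00644). The p53 list had 6 of 30 genes higher and 2 lower, 6 and 2 adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.0448, adjusted p = 0.782 with an estimated correlation). Its call was lost without parental array 3 (0.13) or 4 (0.05) and without alternating array 3 (0.20) or 4 (0.31), and its median was 0.33 without parental array 2. BTG2, a p53-induced antiproliferative gene, rose by 1.65 ± 0.37 (limma adjusted p = 0.00509). Luminal genes had 5 higher and 5 lower of 25, with a median of -0.25, a mean of 0.12 and a camera adjusted p of 0.629, and their median turned to 0.54 after quantile normalization (0.0135). Basal genes had 3 higher and 1 lower of 17, a median of -0.16, a mean of 0.30 and a camera adjusted p of 0.431. Interferon-stimulated genes had 7 higher and 5 lower of 42 (median 0.17, camera adjusted p = 0.0896), and passed with the dark areas left out (median 0.31, adjusted p = 0.0339) and without parental array 1 (0.0273). CMPK2 rose by 1.68 ± 0.25 (limma adjusted p = 0.000411). MUC1, a mucin of luminal cells, rose by 1.75 ± 0.34, and ERBB4 rose by 3.87 ± 0.35 (limma adjusted p = 0.00216 and 5.58e-06). TGFB2 fell by 5.11 ± 0.37 with 3 of 4 alternating arrays above background, ACTG2 fell by 8.97 ± 0.46 and IL20, a cytokine, fell by 7.08 ± 0.68 (limma adjusted p = 8.97e-07, 2.46e-08 and 8.43e-06). NELL2, a secreted neural protein, was at least 15.2-fold higher (limma adjusted p = 4.25e-06).

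The 3974 calls became 2606 without alternating array 1, and the groups lay on different slides. Medians moved by more than 1.5 times for cholesterol (-0.67 after quantile normalization) and DNA replication (-0.73), and with the detected-probe scaling for mitosis (-0.91), estradiol-induced genes (-0.93), genes lower under estradiol (1.25), ribosome biogenesis (-0.87), the p53 list (0.65) and secreted factors (1.15).

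A further comparison asked how cells kept in palbociclib for more than 24 weeks differed from parental cells. Estradiol-induced, interferon-stimulated and basal epithelial genes were lower in the long-term palbociclib cells, and the DNA replication list was lower with fewer members passing. None of these calls held with an estimated correlation (camera adjusted p = 0.456 to 0.782), and the basal and DNA replication calls were also lost in other settings given below. FHL2, a LIM domain cofactor of the estradiol-induced list, fell by 5.18 ± 0.40 on the log2 scale (SE, 4 and 3 arrays), and CCN5, a matricellular protein induced by estradiol, fell by 9.03 ± 0.73 (4 and 4 arrays). Their limma adjusted p-values were 2.28e-06 and 1.04e-06. Of 16391 genes 648 rose and 1256 fell, 1838 of them at least 2-fold. The share that rose was 34.03%, and it was 60.8% in the series matrix values and 50.7% with the detected-probe scaling.

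Of 45 estradiol-induced genes 15 fell and 0 rose, 17 and 1 adjusted over the list alone, with a median of -0.58 (camera adjusted p = 0.000342, adjusted p = 0.497 with an estimated correlation). PGR fell by 6.79 ± 0.48, or -4.01 under normexp, with 1 of 4 long-term arrays above background (limma adjusted p = 5.93e-07). GREB1 had -0.58 (-1.28 without the dark areas), TFF1 0.33 and ESR1 -0.08 (adjusted p = 0.892), and none passed. Interferon-stimulated genes fell, 16 of 42 with 1 rising, 18 and 2 adjusted over the list alone, with a median of -0.71, or -0.44 with the 6 genes below background at their bound (camera adjusted p = 0.00316, adjusted p = 0.676 with an estimated correlation). CMPK2 fell by 2.32 ± 0.25, or -0.71 under normexp and -1.01 in the series matrix values, with 3 of 4 long-term arrays above background (limma adjusted p = 1.72e-05). RSAD2, the antiviral enzyme viperin, was at least 2.14-fold lower with 2 of 4 parental arrays above background, a bound that normexp did not reach (limma adjusted p = 4.77e-05).

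In the basal list 7 of 17 genes fell and 1 rose, 9 and 1 adjusted over the list alone, with a median of -0.98 (camera adjusted p = 0.0497, adjusted p = 0.456 with an estimated correlation). The call was lost with the replicate block (0.0521), without the dark areas (0.0681), and without parental array 2 (0.0951), 3 (0.0965) or 4 (0.0507) or long-term array 1 (0.0529) or 2 (0.0686). CAV1, the main protein of caveolae, fell by 6.27 ± 0.59, LAMB3, a laminin chain, fell by 2.44 ± 0.29 and ANXA1 fell by 2.14 ± 0.37 (limma adjusted p = 8.51e-06, 5.12e-05 and 0.00137). The DNA replication list had 8 of 47 genes lower and 0 higher, 8 and 0 adjusted over the list alone, with a median of -0.62 (camera adjusted p = 0.0257, adjusted p = 0.782 with an estimated correlation). That call was lost without parental array 2 (-0.54, 0.0601), without long-term array 2 (-0.39, 0.172) and with array weights (-0.23, 0.0875). PCNA, the sliding clamp of DNA polymerase, fell by 2.22 ± 0.51, or -1.42 under normexp (limma adjusted p = 0.0109). The mitosis list missed the threshold, with 4 of 50 lower and a median of -0.47 (camera adjusted p = 0.054, 0.00869 without the dark areas, 0.0457 without long-term array 1 and 0.0152 without long-term array 3). MKI67 fell by 1.80 ± 0.37 (limma adjusted p = 0.00594). RB1, the retinoblastoma gene, did not pass at -0.21 (limma adjusted p = 0.786), but dark spots lowered it on parental arrays 1 and 2. It passed at -1.02 without the dark areas (0.00138) and at -0.68 with array weights (0.0247).

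With all spots kept and the 75th percentile as scaling, no other list passed against parental cells, though single members did. ERBB4 rose by 3.18 ± 0.35 and FGFR2, a fibroblast growth factor receptor, fell by 3.10 ± 0.58 (limma adjusted p = 2.29e-05 and 0.00242). TGFB2 fell by 4.25 ± 0.37 and PLK2, a p53-induced kinase, fell by 2.34 ± 0.51 (limma adjusted p = 2.39e-06 and 0.00744). GABARAPL1, an autophagy protein, rose by 2.38 ± 0.38, HLA-DMA, which loads peptides on class II molecules, by 2.08 ± 0.30 and AKR1C1, a steroid reductase, by 2.42 ± 0.55 (limma adjusted p = 0.000645, 0.000402 and 0.00962). NDRG1, a hypoxia-induced gene, rose by 1.66 ± 0.32 (limma adjusted p = 0.00341). The largest rises included APOE, an apolipoprotein, at 4.55 ± 0.56, AOX1, an aldehyde oxidase, at 4.29 ± 0.47, CEMIP, which breaks down hyaluronan, at 4.04 ± 0.34 (1.68 on its other probe) and SPINK4, a protease inhibitor, at 4.61 ± 0.48 (limma adjusted p = 6.72e-05, 2.03e-05, 1.77e-06 and 1.25e-05). KCNK2, a potassium channel, was at least 149-fold lower and CDK14, a cyclin Y dependent kinase, was at least 10.1-fold higher (limma adjusted p = 1.87e-08 and 1.24e-05).

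The 1904 calls became 1169 without parental array 1 and 1134, 1262 and 1264 without long-term array 2, 3 or 4, and the groups lay on different slides. The estradiol-induced median was -0.27 after quantile normalization, the interferon median -0.45, and the basal median -0.39 in the series matrix values.

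The series title asks how the alternating schedule differed from palbociclib alone. This contrast at 10 weeks tests schedule and slide together. Estradiol-induced, interferon-stimulated, basal, lysosome, ribosome biogenesis and cholesterol genes were lower in the alternating cells than in the 10-week palbociclib cells. All these calls were lost with an estimated correlation (camera adjusted p = 0.186 to 0.676), and the lysosome call also under other scalings given below. AREG fell by 9.03 ± 0.67 on the log2 scale (SE, 4 and 4 arrays), and PGR fell by 6.15 ± 0.52 (3 and 4 arrays, 3 of 4 alternating arrays above background). Their limma adjusted p-values were 1.57e-06 and 7.69e-06. Of 16082 genes 868 rose and 1733 fell, 2478 of them at least 2-fold. The share that rose was 33.37%, and it was 63.6% with the detected-probe scaling.

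Of 44 estradiol-induced genes 29 fell and 0 rose, 33 and 0 adjusted over the list alone, with a median of -1.95 (camera adjusted p = 2.24e-14, adjusted p = 0.186 with an estimated correlation). PKIB fell by 3.38 ± 0.30 and GREB1 fell by 4.25 ± 0.96, where alternating array 2 at 4.74 lay above 10-week palbociclib array 3, dark at this spot, at 4.26 (limma adjusted p = 7.69e-06 and 0.00833). ESR1 had 0.50 and did not pass (limma adjusted p = 0.296), and it passed at 0.78 with the dark areas left out (0.0101) and at 1.04 in the series matrix values (0.0316). PSCA, of the genes lower under estradiol, rose by 2.51 ± 0.36 and the interleukin receptor IL1R1 by 2.79 ± 0.56 (limma adjusted p = 0.000595 and 0.0045), while that list missed the threshold at a median of 0.56 (camera adjusted p = 0.0581, or 0.0375 without alternating array 2 and 0.0295 after quantile normalization).

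Interferon-stimulated genes fell, 22 of 42 with 0 rising and 28 adjusted over the list alone, with a median of -1.33, or -0.76 under normexp (camera adjusted p = 1.44e-08, adjusted p = 0.298 with an estimated correlation). IFIT2 and IFIT3, which bind viral RNA, fell by 2.43 ± 0.35 and by a log2 fold change of -2.89 ± 0.41 (limma adjusted p = 0.000616 and 0.000581). Basal genes fell, 7 of 16 with 0 rising and 9 adjusted over the list alone, with a median of -0.95, or -0.56 with the detected-probe scaling (camera adjusted p = 0.00268, adjusted p = 0.236 with an estimated correlation). LAMC2, a laminin chain, fell by 2.58 ± 0.44 (limma adjusted p = 0.00178).

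Of 34 lysosome and autophagy genes 11 fell and 0 rose, 13 and 0 adjusted over the list alone, with a median of -0.79 (camera adjusted p = 0.00214, adjusted p = 0.633 with an estimated correlation). After quantile normalization this list had -0.20 and did not pass (0.127), nor under normexp (-0.20, 0.0896) or in the series matrix values (-0.15, 0.104). GLA, a lysosomal galactosidase, fell by 2.87 ± 0.53 (limma adjusted p = 0.00269). The ribosome biogenesis and MYC list had 7 of 32 genes lower and 0 higher, 13 and 0 adjusted over the list alone, with a median of -0.74, -0.47 without 10-week palbociclib array 3 and -0.44 after quantile normalization (camera adjusted p = 0.00268, adjusted p = 0.676 with an estimated correlation). MYC fell by 1.70 ± 0.35 with alternating array 2 apart at 3.46 (limma adjusted p = 0.00505). Cholesterol biosynthesis fell, 11 of 23 with 0 rising and 12 adjusted over the list alone, with a median of -1.19, or -0.67 after quantile normalization (camera adjusted p = 0.00394, adjusted p = 0.529 with an estimated correlation). HMGCS1, which makes the precursor of mevalonate, fell by 2.13 ± 0.41 (limma adjusted p = 0.00321).

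Histones rose as a list, with 3 of 21 higher and 1 lower, 3 and 1 adjusted over the list alone, and a median of 0.76, or 1.34 after quantile normalization (camera adjusted p = 0.00151, adjusted p = 0.533 with an estimated correlation). DNA replication had a median of 0.34 with 1 gene higher and 2 lower of 47, 0 and 0 adjusted over the list alone (camera adjusted p = 0.0448, adjusted p = 0.782 with an estimated correlation). That call was lost with the replicate block (0.0515) and without 10-week palbociclib array 1 (0.21), 2 (0.22) or 4 (0.15) or alternating array 2 (0.35) or 4 (0.36), and without 10-week palbociclib array 3 the median was 0.60. The mitosis list had a median of 0.06 with 2 of 50 genes higher (camera adjusted p = 0.308, or 0.0316 with a median of 0.27 without 10-week palbociclib array 3 and 0.0424 after quantile normalization), and MKI67 had -0.57 (adjusted p = 0.347), or -0.29 without the dark areas. Drug efflux genes had 4 lower and 1 higher of 21 (median -0.78, camera adjusted p = 0.075, or 0.0301 without 10-week palbociclib array 3 and 0.0375 without the dark areas), among them UGT2B15, which fell by 4.27 ± 0.39, and the quinone reductase NQO1, which fell by 2.42 ± 0.44, each over 3 values in 10-week palbociclib cells (limma adjusted p = 1.66e-05 and 0.00278). CHRD, a BMP antagonist, rose by 3.41 ± 0.42, LDLRAD4, an inhibitor of TGF-beta signalling, by 3.62 ± 0.32 and TESC, a calcium-binding protein, by 3.48 ± 0.42 (limma adjusted p = 0.00021, 7.69e-06 and 0.000136). IL20 fell by 8.84 ± 0.68 (limma adjusted p = 1.89e-06), and SLC37A2, a sugar phosphate transporter, was at least 17.5-fold higher (limma adjusted p = 6.12e-05).

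The 2601 calls became 1285 without alternating array 1, 1622 without array 3 and 1289 in a fit of these groups alone. The groups lay on different slides.

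**Figure D4:**
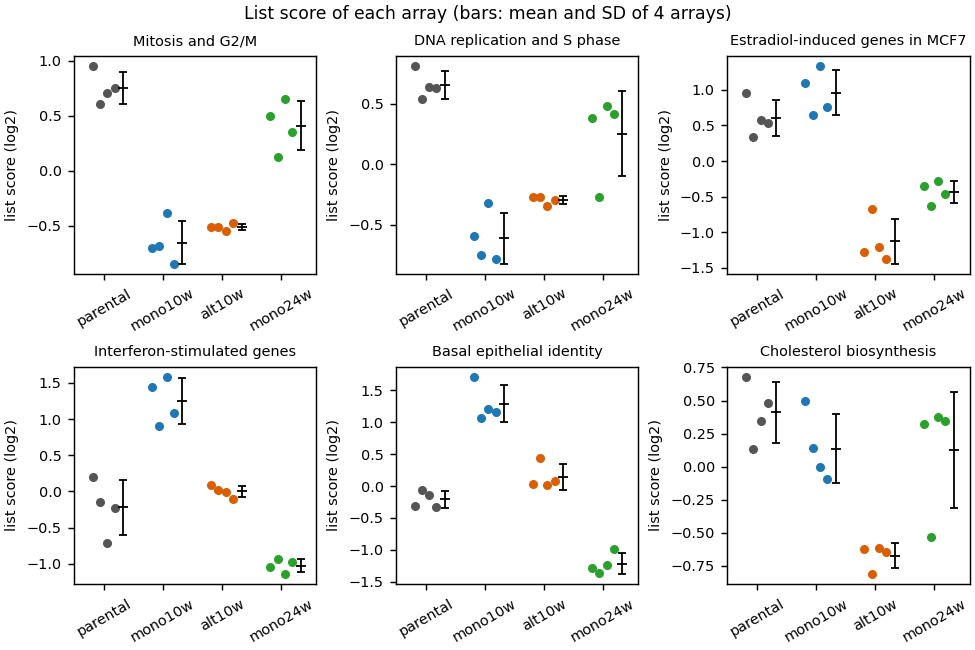
Score of 6 gene lists on each array (mean of member genes, log2 units, relative to the mean of all arrays) by group, with the mean and SD of 4 arrays. In 10-week palbociclib cells the mitosis and DNA replication scores lie below those of parental cells and the interferon and basal scores above them, while long-term palbociclib cells have the lowest interferon and basal scores.

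The contrast of long-term with 10-week palbociclib cells asked how these forms of palbociclib treatment differed, and dose (500 and 750 nM) and duration changed together in it. Mitosis, DNA replication and histone genes were higher in the long-term palbociclib cells, and interferon-stimulated, basal, estradiol-induced and luminal genes were lower. No list kept its call with an estimated correlation (camera adjusted p = 0.159 to 0.533). FOXM1 rose by 1.82 ± 0.26 on the log2 scale (SE, 4 and 3 arrays), and ANXA1 fell by 4.78 ± 0.37 (4 and 4 arrays). Their limma adjusted p-values were 0.00024 and 3.1e-07. Of 16083 genes 1283 rose and 2214 fell, 3266 of them at least 2-fold. The share that rose was 36.69%, and it was 59% in the series matrix values and 52.1% with median centring.

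Of 50 mitosis genes 21 rose and 0 fell, 28 and 1 adjusted over the list alone, with a median of 1.02 (camera adjusted p = 3.22e-09, adjusted p = 0.288 with an estimated correlation). NDC80 rose by 1.68 ± 0.24 and KIF2C, a mitotic kinesin, by 1.71 ± 0.36 (limma adjusted p = 0.000151 and 0.00336), while MKI67 had -0.43 (adjusted p = 0.439), or -0.15 without the dark areas. Of 47 DNA replication genes 13 rose and 0 fell, 15 and 0 adjusted over the list alone, with a median of 0.66, or 1.05 with array weights (camera adjusted p = 2.85e-06, adjusted p = 0.497 with an estimated correlation). EXO1 rose by 1.63 ± 0.23, DTL, a ubiquitin ligase subunit that limits replication licensing, by 1.36 ± 0.26 and DHFR by 2.03 ± 0.38 (limma adjusted p = 0.000121, 0.00166 and 0.00178). Histones rose, 6 of 21 with 2 falling, 9 and 2 adjusted over the list alone, with a median of 1.12 (camera adjusted p = 0.00151, adjusted p = 0.533 with an estimated correlation). H4C2 rose by 2.40 ± 0.51 and H2BC6, another core histone, by 2.02 ± 0.52 (limma adjusted p = 0.00395 and 0.0125). In the cyclin list 6 rose and 4 fell of 35 (camera adjusted p = 0.0896). Its p was 0.0276 without long-term array 2 and 0.033 with array weights. The CDKN2A probe had -1.74 ± 0.35 (limma adjusted p = 0.0023), and whether it read CDKN2A was untested.

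Interferon-stimulated genes fell, 28 of 42 with 0 rising and 29 adjusted over the list alone, with a median of -1.95, or -1.91 at the bounds and -1.30 under normexp (camera adjusted p = 6.84e-15, adjusted p = 0.21 with an estimated correlation). RSAD2 was at least 24.3-fold lower and IFIT3 at least 22.1-fold lower, both without any long-term array well above background, and normexp did not reach these bounds (limma adjusted p = 1.77e-08 and 1.6e-07). Basal genes fell, 11 of 16 with 0 rising and 12 adjusted over the list alone, with a median of -2.58 (camera adjusted p = 6.48e-07, adjusted p = 0.159 with an estimated correlation). LAMB3 fell by 2.78 ± 0.29 (limma adjusted p = 8.04e-06). Estradiol-induced genes fell, 19 of 44 with 0 rising and 20 adjusted over the list alone, with a median of -0.89, or -0.56 in the series matrix values (camera adjusted p = 4.39e-06, adjusted p = 0.36 with an estimated correlation). FHL2 fell by 4.54 ± 0.40 over 3 values in 10-week palbociclib cells and CCN5 fell by 6.25 ± 0.73 (limma adjusted p = 3.43e-06 and 2.22e-05). PGR fell by 7.03 ± 0.48, or -4.35 under normexp, with 1 of 4 long-term arrays above background (limma adjusted p = 1.91e-07). Luminal genes fell, 8 of 25 with 0 rising and 8 adjusted over the list alone, with a median of -0.65, or -0.43 without 10-week palbociclib array 3 (camera adjusted p = 0.0105, adjusted p = 0.288 with an estimated correlation). MUC1 fell by 1.61 ± 0.34 (limma adjusted p = 0.00322).

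Senescence-associated secreted factors fell, 6 of 18 with 1 rising, 6 and 1 adjusted over the list alone, with a median of -0.78 (camera adjusted p = 0.0245, adjusted p = 0.269 with an estimated correlation). This call was lost without 10-week palbociclib array 2 (-0.81, 0.0714) and after quantile normalization (-0.60, 0.0668). PLAT was at least 11.8-fold lower, and TNFRSF11B, a decoy receptor for RANKL, fell by 2.10 ± 0.38 (limma adjusted p = 1.99e-07 and 0.00115). Leukocyte markers had a median of -1.77 with 2 of 5 lower and 2 adjusted over the list alone (camera adjusted p = 0.0232, adjusted p = 0.25 with an estimated correlation), a call lost with the dark areas left out (0.0996), and the median was -1.03 without long-term array 2. CD79A, a B cell receptor component, fell by 3.18 ± 0.55 (limma adjusted p = 0.000793). PSPH and PSAT1, of serine synthesis, rose by 2.19 ± 0.37 and 1.73 ± 0.31 (limma adjusted p = 0.000688 and 0.00123). UGT2B15 fell by 6.43 ± 0.39 over 3 values in 10-week palbociclib cells (limma adjusted p = 6.25e-08). The largest falls included CDSN, corneodesmosin, at -9.87 ± 0.66 and KRT9 at -7.52 ± 0.44, and the largest rises PTGER2, a prostaglandin receptor, at 4.45 ± 0.41 and APOE at 4.56 ± 0.56 (limma adjusted p = 7.39e-08, 2.3e-08, 2.12e-06 and 4.11e-05). The kallikrein KLK11 was at least 120-fold lower and the transcription factor TCF4 at least 28.4-fold higher (limma adjusted p = 9.02e-11 and 2.18e-07).

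The 3497 calls became 2292 in a fit of these groups alone, and the groups lay on different slides.

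The added contrast compared alternating with long-term palbociclib cells within slide 2. Mitosis, ribosome biogenesis, DNA replication and cholesterol genes were lower in the alternating cells, and interferon-stimulated, basal and estradiol-repressed genes were higher. The lists did not pass with an estimated correlation (camera adjusted p = 0.363 to 0.534). PSCA rose by 4.14 ± 0.36 on the log2 scale and SGCE, a sarcoglycan, fell by 7.03 ± 0.42 (SE, 4 and 4 arrays, limma adjusted p = 1.01e-06 and 4.74e-08). Of 16464 genes 1282 rose and 1361 fell, 2482 of them at least 2-fold. The share that rose was 48.51%, 64.6% with the detected-probe scaling and 36.7% with median centring.

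Of 50 mitosis genes 14 fell and 0 rose, 25 and 0 adjusted over the list alone, with a median of -0.98 (camera adjusted p = 9.19e-08, adjusted p = 0.363 with an estimated correlation). NDC80 fell by 1.08 ± 0.24 and HMMR, a spindle protein, fell by 1.44 ± 0.33 (limma adjusted p = 0.00572 and 0.00649). DNA replication fell, 6 of 47 with 0 rising and 5 adjusted over the list alone, with a median of -0.56, or -0.31 with the detected-probe scaling (camera adjusted p = 0.00149, adjusted p = 0.534 with an estimated correlation). Long-term array 2 scored -0.27 on this list, within the alternating range. UNG, a uracil DNA glycosylase, fell by 1.62 ± 0.27 (limma adjusted p = 0.00104). Ribosome biogenesis fell, 14 of 32 with 0 rising and 16 adjusted over the list alone, with a median of -1.03 (camera adjusted p = 2.46e-06, adjusted p = 0.367 with an estimated correlation). ODC1, of polyamine synthesis, fell by 1.97 ± 0.31 and MYC fell by 1.46 ± 0.35 with alternating array 2 apart at 3.46 (limma adjusted p = 0.000407 and 0.00938). Cholesterol biosynthesis fell, 5 of 23 with 0 rising and 5 adjusted over the list alone, with a median of -0.80, or -0.52 after quantile normalization (camera adjusted p = 0.00149, adjusted p = 0.376 with an estimated correlation). STARD4, a sterol carrier, fell by 2.07 ± 0.43 (limma adjusted p = 0.00366). The unfolded protein list fell, 9 of 31 with 0 rising and 11 adjusted over the list alone, with a median of -0.52, or -0.27 with the detected-probe scaling (camera adjusted p = 0.00149, adjusted p = 0.367 with an estimated correlation). PSPH fell by 2.64 ± 0.37 and PSAT1 fell by 2.51 ± 0.31 (limma adjusted p = 0.000143 and 5.43e-05).

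Estradiol-induced genes fell, 9 of 45 with 3 rising, 12 and 4 adjusted over the list alone, with a median of -0.53, or -0.28 with the detected-probe scaling and -0.35 under normexp (camera adjusted p = 0.0158, adjusted p = 0.534 with an estimated correlation). AREG fell by 8.06 ± 0.67, PKIB fell by 2.98 ± 0.30 and GREB1 fell by 3.80 ± 0.96 with alternating array 2 apart at 4.74 (limma adjusted p = 7.65e-07, 5.21e-06 and 0.0126). PGR, low in both groups, had 0.88 and did not pass (limma adjusted p = 0.288), but passed without long-term array 1 (1.43, 0.0345). It had 0.06 after quantile normalization. Genes reported to be lower under estradiol rose, 10 of 21 with 1 falling, 11 and 1 adjusted over the list alone, with a median of 1.08 (camera adjusted p = 0.00049, adjusted p = 0.363 with an estimated correlation). YPEL3 rose by 1.77 ± 0.29 (limma adjusted p = 0.000568). Interferon-stimulated genes rose, 14 of 42 with 2 falling, 18 and 3 adjusted over the list alone, with a median of 0.72, or 0.67 at the bounds (camera adjusted p = 7.04e-06, adjusted p = 0.367 with an estimated correlation). CMPK2 rose by 3.99 ± 0.25, or 1.97 under normexp, with 3 of 4 long-term arrays above background, and RSAD2 was at least 4.61-fold higher, a bound not reached under normexp (limma adjusted p = 5.83e-08 and 1.15e-06). Basal genes rose, 7 of 17 with 1 falling, 10 and 3 adjusted over the list alone, with a median of 1.35, or 0.12 under normexp (camera adjusted p = 0.0012, adjusted p = 0.363 with an estimated correlation). ANXA1 rose by 3.53 ± 0.37, ITGB4 by 2.10 ± 0.33 and CAV1 by 4.23 ± 0.64 over 3 alternating values (limma adjusted p = 7.17e-06, 0.000359 and 0.000367). Secreted factors rose, 6 of 18 with 0 falling, 6 and 3 adjusted over the list alone, with a median of 0.95, or 0.78 at the bounds (camera adjusted p = 0.0265, adjusted p = 0.363 with an estimated correlation), and their median was 0.54 without alternating array 3. PLAU, urokinase, was at least 10.9-fold higher (limma adjusted p = 5.68e-06). CALML5, an epidermal calmodulin, rose by 5.62 ± 0.48 and LAMB1, a laminin chain, fell by 5.13 ± 0.34 (limma adjusted p = 9.14e-07 and 1.03e-07).

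The call of the secreted factors was lost after quantile normalization (0.0538), and their median turned to -0.34 over probes well above background on all 16 arrays (0.702). The 2643 calls became 1694 without long-term array 3 and 6500 in a fit of these groups alone, and the fit with slide as a block gave 2643.

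**Figure D5:**
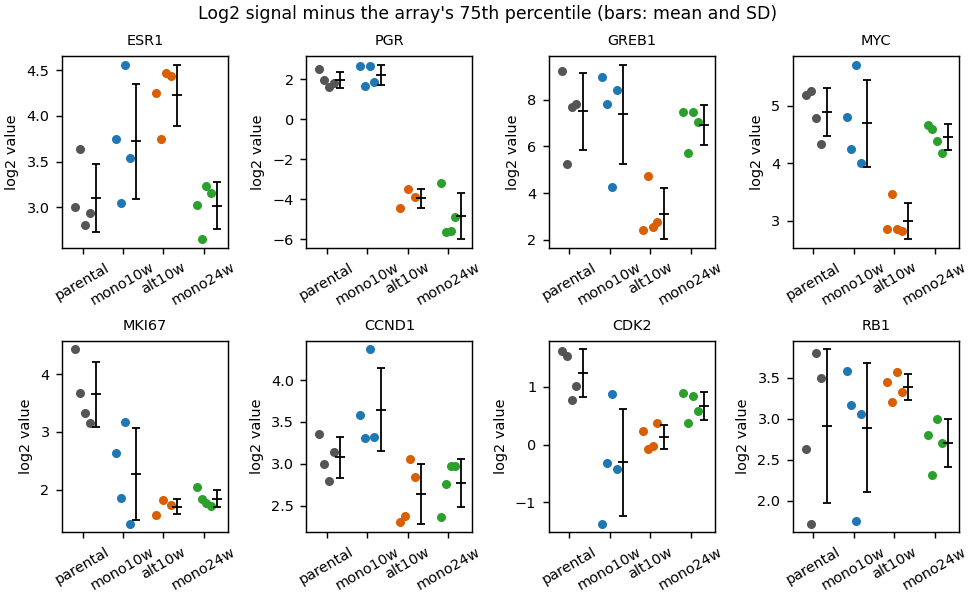
Log2 value of 8 genes of the fixed panel on each array by group, relative to the array's 75th percentile, with the mean and SD of 4 arrays. PGR is lower in alternating and long-term palbociclib cells, and GREB1 and MYC have alternating array 2 apart at 4.74 and 3.46. Dark spots lower RB1 on parental arrays 1 and 2 and 10-week palbociclib array 3.

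The calls of the treated groups against the same parental arrays were also compared. Genes that rose in both the 10-week palbociclib and the alternating cells numbered 442, where independent lists give 68.72, and genes that fell in both numbered 446, where independent lists give 133.1. In opposite directions 24 genes were called, or 115 with the dark areas left out. Simulated unchanged groups against these parental arrays shared a median of 0 calls in the same direction. Against split parental arrays, each group with its own pair, 340.5 genes at the median of 6 splits were called in the same direction, compared with 888 against all of them. Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.513 (0.592 in simulations without effects, so below it) and a covariance of 0.622 (0.22 in simulations), a difference of 0.403. Between 10-week and long-term palbociclib cells 189 genes rose in both (independent lists 32.91), 182 fell in both (63.79) and 118 were called in opposite directions (391 with the dark areas left out), with 371 in the same direction and 138.5 against split parental arrays. The simulated median was again 0, and here the correlation was 0.281 (0.592 in simulations without effects, so below it) and the covariance 0.321, 0.101 above the simulated one. Without 10-week palbociclib array 3 the same-direction counts were 2461 and 1179, and without parental array 1 the second count was 235.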

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

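The tests of dark areas, scaling and slide below were chosen only after the results were seen, while the test of the high negative-control signal and the splits were written before. An array was picked out when its gap to the nearest of its group exceeded Dixon's 95% critical value, as a share of the group's range. Chance does this in about 1 in 20 groups, and 25 of the 188 groups tested had such an array.

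The ratio of the 99th to the 75th percentile was 633.6 on parental array 1 (others 380.6 to 410.4) and 280.8 on alternating array 2 (167.1 to 177.6). The net signal of negative controls was 26.44 on alternating array 4 (22.36 to 22.79). Dark areas covered 27.24% of 10-week palbociclib array 3 (0 to 0.813%). The mean correlation with the own group was 0.9042 on parental array 2 (0.9411 to 0.9478) and 0.8617 on 10-week palbociclib array 3 (0.9333 to 0.9403).

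Through the scaling, dark areas had raised the values outside them on parental array 2 and 10-week palbociclib array 3. Scores of whole lists stood apart on single arrays. On parental array 1 these were lysosome at 0.5418 (-0.009825 to 0.06221) and drug efflux at 0.1636 (-0.3975 to -0.3174), and on parental array 2 genes lower under estradiol at -0.0894 (-0.6931 to -0.6033). On 10-week palbociclib array 1 luminal genes had 0.603 (0.2163 to 0.2687) and leukocyte markers 1.99 (1.111 to 1.233), and on array 3 p53 targets had 0.8535 (-0.07802 to 0.07125). On alternating array 2 basal genes had 0.4391 (0.01933 to 0.07794) and cholesterol -0.814 (-0.6436 to -0.6174). On long-term array 2 DNA replication had -0.2734 (0.3845 to 0.4796), mesenchymal genes -0.2536 (-0.7317 to -0.6969), p53 targets 0.2792 (-0.2619 to -0.1743) and cholesterol -0.5345 (0.3228 to 0.3733). On long-term array 4 receptor tyrosine kinases had 0.1073 (-0.05078 to -0.0252).

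Among panel genes the log2 value stood apart for CCNE1 on parental array 1 at 5.293 (4.384 to 4.536), CDK6 on parental array 2 at 3.693 (2.646 to 2.809) and E2F1 on 10-week palbociclib array 3 at 2.473 (1.075 to 1.265). It also did for GREB1 at 4.741 (2.417 to 2.768) and MYC at 3.464 (2.816 to 2.855) on alternating array 2, and for EGFR on long-term array 2 at -3.729 (-2.274 to -2.091).

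Some values against parental cells had opposite signs in different treated groups, and the direct contrast of those groups passed its limma or camera test. The list contrasts did not pass with an estimated correlation (camera adjusted p = 0.159 to 0.36). In 10-week palbociclib cells the estradiol-induced list (camera adjusted p = 0.0921) and PGR (limma adjusted p = 0.807) did not pass against parental cells. The list did pass there without the dark areas (0.0341) and after quantile normalization (0.0295), so an opposite direction of these genes stays open, and none was shown for PGR. Estradiol-induced genes had medians of -1.394 in alternating and 0.346 in 10-week palbociclib cells (direct contrast -1.953), and -0.5842 in long-term cells (direct contrast -0.8943). Basal genes had -0.9763 in long-term and 1.844 in 10-week palbociclib cells (-2.577), and interferon-stimulated genes -0.7128 and 1.234 (-1.953). PGR had -5.908 in alternating, -6.787 in long-term and 0.2413 in 10-week palbociclib cells, with direct contrasts of -6.149 and -7.028. Only 1 of 4 long-term and 3 of 4 alternating arrays had PGR above background, and normexp gave -4.01 against parental and -4.35 against 10-week palbociclib cells for the long-term cells, so the sizes are uncertain. Called in opposite directions were 24 genes between alternating and 10-week palbociclib cells and 118 between long-term and 10-week palbociclib cells.

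Of 7871 kept probes without a gene name, 322 changed in 10-week palbociclib, 985 in alternating and 403 in long-term cells against parental cells. Between alternating and 10-week palbociclib cells 1168 did, between long-term and 10-week palbociclib cells 1251, and between alternating and long-term cells 597.

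More genes fell than rose in alternating against parental cells, where 34.05% of the calls rose. With the dark areas left out 39.8% rose, which argues against dark areas as the whole cause. The highest share over other scalings was 64.2%, and leaving out the dark areas with quantile normalization gave 50.6%. The scaling may therefore account for the excess of falls, and its direction is not used here as a finding.

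Mitosis genes were higher in long-term than in 10-week palbociclib cells, with a median of 1.02. It was 1.181 with the dark areas left out and at least 0.9997 under every other scaling, which argues against both as the cause. The groups lay on different slides, and within slide 2 the alternating cells had -0.9797 against the long-term cells. Slide and treatment cannot be told apart here, because no array of either group was on the other slide. Dose and duration changed together and cannot be told apart either.

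Interferon-stimulated genes were higher in 10-week palbociclib than in parental cells. The median was 1.184 with the dark areas left out, and 1.316 without parental array 1 and 10-week palbociclib array 1, whose negative controls had the highest signal. These values argue against the dark areas and the high negative-control signal as the cause. Both groups lay on slide 1, so a difference between slides does not enter this contrast by design, and its median of 1.234 is the pattern itself and tests nothing. No biological explanation was tested.

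Each comparison was also counted over the 35 splits of its 8 arrays into 4 and 4. For 10-week palbociclib against parental cells 3 of the 35 splits gave at least the 1676 genes, and chance was not excluded. The highest other split had 3006 genes, and 2152 against 1618 for changes of at least 2-fold, where again 3 splits were as large. That split set parental arrays 1, 2 and 4 and 10-week palbociclib array 3 against the rest and so followed the dark areas. With the dark areas left out only the real split gave as many, with 4280 genes against 389 at most. For at least 2-fold it had 2494 against 348. This argues against chance, though in a setting chosen after the arrays had been seen. In the other comparisons only the real split gave as many genes, at 1 of 35 the lowest possible share. This argues against chance but excludes neither it nor, across slides, a slide effect. The highest other split had 47 genes against 3974 for alternating and 0 against 1904 for long-term cells, both versus parental cells. Versus 10-week palbociclib cells it had 3 against 2601 and 11 against 3497 in this order, and 0 against 2643 between alternating and long-term cells. Those numbers were the same for at least 2-fold, against 3647, 1838, 2478, 3266 and 2482.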

How the results depend on the processing

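The contrast of alternating with long-term cells, the settings that leave out dark areas or the darkest arrays, and the scaling over detected probes were chosen after seeing the data. Counts below are in the order 10-week palbociclib, alternating and long-term against parental cells, alternating and long-term against 10-week palbociclib cells, and alternating against long-term cells. Same-direction counts follow for 10-week palbociclib with alternating and with long-term cells. Where no cause is given, the cause was not tested.

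With the dark areas left out 4280, 6705, 4396, 5289, 6364 and 6044 genes changed, 2494 at least 2-fold in the first comparison, and 2574 and 1244 were shared. Quantile normalization with the dark areas left out gave 4024, 6012, 4266, 5054, 6384 and 5669 genes, 7 lists in long-term against parental cells, and 2249 and 1153 shared. Without parental array 2 and 10-week palbociclib array 3 the counts were 3795, 6869, 4723, 4405, 5857 and 5805, with 2664 and 3307 at least 2-fold in 10-week and long-term against parental cells, and 2436 and 1230 shared. Array weights gave 4874, 7183, 5145, 5673, 7289 and 8153, with 2752, 2829 and 4264 at least 2-fold in 10-week and long-term against parental and in alternating against long-term cells, 2 lists in long-term against parental cells, and 3069 and 1559 shared. The weights were lowest for 10-week palbociclib array 3 (0.0575) and parental array 2 (0.145).

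A fit of only the groups compared, with fewer arrays, gave 249 genes in the first comparison (249 at least 2-fold), 1289 (1289) in alternating and 2292 in long-term against 10-week palbociclib cells, 6500 (3746) in the last, and 177 and 90 shared. Normexp gave 2290 and 1621 genes of at least 2-fold in alternating against parental and against 10-week palbociclib cells. With the correlation estimated, 0 lists passed in each of the 6 comparisons, and fry called 8 in long-term against parental and 13 in alternating against 10-week palbociclib cells. Split parental arrays gave 340.5 and 138.5 shared genes.

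Leaving out 1 array at a time gave from 1226 (without parental 4) to 3806 (without 10-week palbociclib 3) genes in the first comparison. Of at least 2-fold there were 1223 to 2818. Alternating against parental cells ranged from 2606 to 3770. Long-term against parental cells ranged from 1134 to 2117, with 1128 to 2066 at least 2-fold and 2 to 5 lists. Alternating against 10-week palbociclib cells ranged from 1285 to 3001, with 1281 to 2802 at least 2-fold, and alternating against long-term cells from 1694 to 2356. Shared genes ranged from 653 to 2461 and from 235 to 1179. For named genes, 291 such results lost their call, 12 gained one and 3859 kept their side of the threshold.

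The direction of the test turned in 4 results where a call was made in either setting. TFEB in long-term against parental cells was -0.9438 and 0.1891 with the mean of a gene's probes, which adds probes that differ. Leukocyte markers in the first comparison turned from 1.389 to -0.3274 with the dark areas left out and to -0.4366 with quantile normalization added. In long-term against parental cells that list had a median of -0.1544 and a mean of 0.03, and that last setting gave -0.7097. The median changed sign but the direction of the test did not for secreted factors in alternating against parental cells (-0.24 with no filter on dim probes) and against long-term cells (-0.34 over probes above background on all arrays), and luminal genes in alternating against parental cells (0.51 to 0.65 under other scalings). The same held for leukocyte markers (-0.22 with no filter), hypoxia (-0.01 without 10-week palbociclib array 3) and luminal genes (-0.00 with the dark areas left out) in the first comparison, and interferon-stimulated genes in alternating against parental cells (-0.03 over probes above background on all arrays).

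The share of calls that rose was 34.05% in alternating against parental cells and 64.2% with the detected-probe scaling, 48% in the series matrix values and 50.6% with the dark areas left out and quantile normalization. Settings moving it by over 10 percentage points gave 44.1% to 60.8% in long-term against parental cells (34.03%), 46.6% to 63.6% in alternating against 10-week palbociclib cells (33.37%), 46.8% to 59% in long-term against 10-week palbociclib cells (36.69%), and 36.7% to 64.6% in the last comparison (48.51%). Scalings moved the median of all genes by up to 0.477.

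For called genes with a printed value, another probe differed by over 1.5 times for CDK1 (-0.90) and DHFR (-1.43) in the first comparison, GREB1 (-2.47) in alternating and MKI67 (-1.09) in long-term against parental cells. It also did for GREB1 (-2.76), IL1R1 (1.53) and CHRD (2.21) in alternating, and DHFR (0.87), FHL2 (-6.86) and MUC1 (-1.04) in long-term against 10-week palbociclib cells, and for GREB1 (-2.02) in the last comparison.

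The replicate numbers do not pair the samples, since in no comparison did every same-number correlation exceed 0.1. Arrays correlated highest with the array of their own number in 1, 0, 2, 0, 1 and 0 of 8 cases, and in 2, 0, 3, 0, 2 and 0 with the dark areas left out. Same-number correlations were then highest in 10-week palbociclib (0.378, 0.156, -0.000686 and 0.0991) and long-term cells (0.168, 0.231, 0.0554 and 0.133) against parental cells. With the replicate number as a block 1451, 3671, 1673, 2448, 3165 and 2305 genes changed, and 2 list calls were lost. Slide as a block could not be fitted across slides, and within a slide it gave 1676 and 2643. Signal over background limited the test to 29748 of 58201 probes, and under normexp every gene the report gives as an at-least fold changed by less than that bound. For RSAD2 normexp gave log2 fold changes of -0.78 in long-term against parental cells, -2.49 in long-term against 10-week palbociclib cells and 0.81 in alternating against long-term cells.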
